A study of Rattus norvegicus with 6 samples.

How the data were processed

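RNA from the spinal cord of Sprague-Dawley rats, an outbred laboratory stock, was sequenced in 6 libraries. All animals were of the F3 generation, 3 generations after their F0 ancestors. Per the labels, 3 libraries came from descendants of an F0 control lineage and 3 from descendants of an F0 folate lineage; the titles call the second group folic-acid-treated. Per the labels' protocols, about 100 ng of total RNA entered a NuGen kit primed with random primers, and 100-cycle single-end reads came from an Illumina HiSeq2500. The protocol text speaks of mice where the organism field gives rat, and of combinations of animals without saying which. Whether a library holds 1 animal or a pool is therefore not given in the sources used here. No label gives sex, litter, level of the cord, batch or date. P-values measure only the spread between these libraries.

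The submitters' processing notes name FastQC, STAR 2.7.0, RSEM 1.3.1 and the rat build rn6, with no settings. Per the file headers, each library has a deposited RSEM table with an expected count, a TPM value, an FPKM value, a length and an effective length per row. The deposited expected counts are RSEM's estimates of the reads from each row and are fractional where reads were shared between rows. Deposited TPM and FPKM were scaled within each library by the authors' RSEM run. The TPM values served for one alternative test and for describing the most abundant transcripts, and the FPKM values were not tested. In all 40808 rows the gene identifier equals the transcript identifier. The quantified unit is therefore an Ensembl transcript, and isoforms of a gene compete for its reads. On transcripts longer than 3000 bases, effective length was shorter than length by 232.91 to 255.27 bases, a different number in each library. How these values were set for single-end reads is not given in the sources used here.

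The files pair no transcript with a gene name. The reference table of 47357 genes used here carries no Ensembl transcript identifiers, so 0 of the 40808 rows were matched to a symbol, a genomic position or a gene. The lists of pathway and cell type genes fixed before the data were examined could therefore not be tested. The rule for named genes required a symbol and selected none. In its place the 2 transcripts with the smallest p in each direction are named by identifier, a rule set after the data were examined.

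Expected counts were rounded to whole numbers. Transcripts with low counts were removed with filterByExpr, which left 17433 transcripts holding 99.89% of all counts. Counts were normalised by TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersion, intercept and lineage, all 6 libraries). Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are folate lineage over control lineage, and the standard error is the one implied by the F statistic. Errors of CPM values are SD over 3 libraries. Where a group had no counts, a fold was computed against a floor of 3 counts over the group; intervals and floors of this kind cover counting error only.

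Libraries were compared by Pearson correlation and principal components of log2 CPM (prior count 2). The distance between lineages was tested by an exact permutation test over the 10 splits of 6 libraries into 3 and 3, whose smallest p is 0.1. The same 10 splits were refitted for every count of calls. Within each group, all pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 18.13 to 35.7). Replicate numbers 1 to 3 occur in both groups, but the deviations of same-numbered libraries correlated at 0.0174, 0.00024 and -0.0491, so the numbers were not treated as pairs.

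Alternatives fixed before the data were examined were other normalisations, DESeq2 1.42.0, limma 3.58.1 (voom, and log2(TPM + 1) with a trend), other filters and thresholds, an offset for effective length, a replicate block and leaving out each library. Alternatives that need gene names (all set tests, and leaving out sex-linked, haemoglobin and mitochondrial genes) were not run. Expected counts were taken as whole when within 0.005 of a whole number in all 6 libraries.

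The tests were run on simulated data with the means, dispersions and library sizes of the 17433 transcripts. The changed transcripts were drawn only from those with a mean of at least 1 CPM, so recovery below that level was not measured. Over 3 simulations with 200 transcripts changed in each, edgeR recovered 16.92% of the 1.5-fold changes, 46.27% of the 2-fold changes and 73.23% of the 4-fold changes. It called 37 of 51699 unchanged transcripts. DESeq2 recovered 29.35%, 57.21% and 81.82% and called 198 unchanged transcripts.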

Results

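Spinal cord transcripts were measured in 6 libraries from F3 rats, 3 descended from an F0 control lineage and 3 from an F0 folate lineage. Control libraries held 19364235 ± 1898931 expected counts and folate-lineage libraries 18341955 ± 1799494 (SD, n = 3 each). The range over all libraries was 16505715 to 21131429. Of the 40808 transcripts listed, 23869 had a count in at least 1 library. A library of the control lineage detected 20182 ± 287 transcripts and one of the folate lineage 20323 ± 292 (SD, n = 3 each). Expected counts were whole numbers in all 6 libraries for 9611 of the 17433 transcripts tested (55.1%). The other tested transcripts shared reads with similar transcripts in at least 1 library.

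A small set of transcripts dominated the libraries in both lineages. The 20 most counted transcripts of each library took 26.1 ± 2.18% of its counts in the control lineage and 27.7 ± 2.08% in the folate lineage (SD, n = 3 each). This difference was within the spread between libraries (exact permutation test, two-sided, p = 0.5). Among the 20 transcripts with the highest mean TPM, changes estimated from counts lay between -0.46 and 0.44 on the log2 scale, and the smallest adjusted p was 0.486 in edgeR. For 3 of the 20, of 204, 305 and 297 bases, the count-based estimate was negative (-0.46, -0.14 and -0.08) while the mean TPM was higher in the folate lineage, so their direction depended on the scale. The first of them, at -0.46, stood at 23408 ± 3137 TPM in the control lineage and 25985 ± 5881 TPM in the folate lineage (SD, n = 3 each). The largest positive estimate belonged to a transcript of 2082 bases, at 21318 ± 2211 TPM in the control lineage and 29723 ± 3107 TPM in the folate lineage (SD, n = 3 each). A transcript of 2037 bases stood at 13464 ± 1031 and 18284 ± 2112 TPM. Of the 20, these 2 alone had an unadjusted p under 0.05 in edgeR, and neither passed the adjusted threshold (adjusted p = 0.486 for each).

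The lineages were first compared as whole profiles, to ask whether descent from folate-treated ancestors goes with a different spinal cord transcriptome. On average, libraries of the same lineage were only slightly more alike than libraries of different lineages, and folate replicate 3 was an exception. The mean correlation of log2 CPM was 0.934 within the control lineage (3 pairs) and 0.934 within the folate lineage (3 pairs). Between lineages it was 0.929 over 9 pairs, with a range of 0.919 to 0.943 that covers both within-lineage means. Folate replicate 3 correlated more closely with control replicates 1 and 2 (0.942 and 0.943, the highest of all pairs) than with folate replicates 1 and 2 (0.938 and 0.933). The first principal component held 25.8% of the variance and the second 20.9%. Components 3, 4 and 5 held 20.3%, 18.2% and 14.7%, so no single component dominated. On the first component, the control libraries lay at -64.8, -24.0 and -12.9 and the folate libraries at 7.42, 41.7 and 52.5. The mean distance between lineages exceeded that within lineages by 3.60, against at most 1.19 in the other 9 splits of the libraries. The exact permutation p was 0.1, the smallest that 3 libraries against 3 allow.

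**Figure D1:**
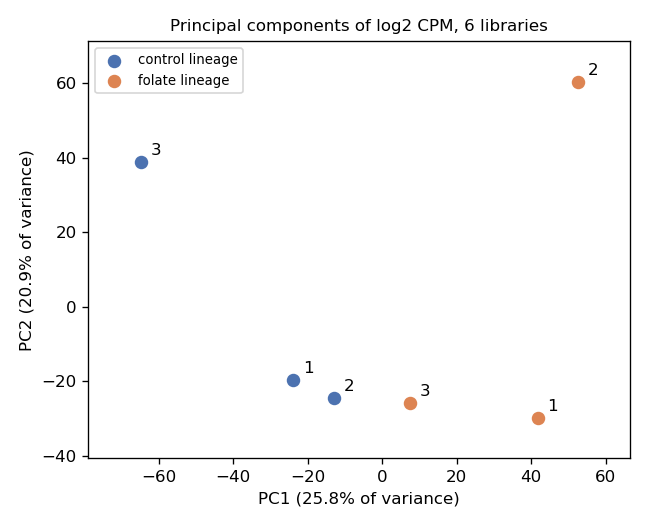
Each point is 1 library (number, replicate) on the first principal component (x, 25.8% of variance) and the second (y, 20.9% of variance) of log2 CPM, with no unit. The 3 control libraries lie at -12.9 or below on the first component and the 3 folate-lineage libraries at 7.42 or above, while control 3 and folate 2 lie apart from the rest on the second.

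Transcript by transcript, 2 of the 17433 transcripts tested were higher in the folate lineage and 0 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Counting the lineage split itself, 3 of the 10 splits of the libraries gave 2 or more edgeR calls. A split that mixed the lineages gave 5, so the number of calls does not set the lineage split apart. ENSRNOT00000001277.3, a transcript of 2730 bases, rose from 11.4 ± 1.79 CPM in the control lineage to 43.0 ± 4.52 CPM in the folate lineage (SD, n = 3 each). Its log2 fold change was 1.92 with a standard error of 0.15, a 3.79-fold rise, and its adjusted p in edgeR was 0.0130. ENSRNOT00000016121.5, of 2439 bases, rose from 16.2 ± 1.07 to 61.0 ± 10.9 CPM (SD, n = 3 each). Its log2 fold change was also 1.92, with a standard error of 0.15 and an adjusted p of 0.0130 in edgeR. All 3 folate-lineage libraries exceeded all 3 control libraries for both. The first had 173 to 264 counts per control library and 654 to 958 per folate-lineage library, whole numbers throughout. The second had 287 to 345 and 830 to 1331 counts, and its expected counts were fractional in at least 1 library. Per library, the second stood at 1.27 to 1.66 times the CPM of the first.

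Leaving out any 1 of 5 of the libraries took the adjusted p of both above 0.05, in fits that hold fewer libraries. Without folate replicate 3 both still passed in edgeR. For ENSRNOT00000001277.3 the adjusted p was 0.0508, 0.129 and 0.0903 without control replicates 1, 2 and 3, and 0.0669 and 0.0539 without folate replicates 1 and 2. For ENSRNOT00000016121.5 the values in the same order were 0.0732, 0.15, 0.0903, 0.0688 and 0.0539. The estimated rises stayed between 1.76 and 2.06 on the log2 scale in the 17 alternatives that estimated them again, the lowest being on the log2(TPM + 1) scale.

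On the lower side, the smallest adjusted p in edgeR was 0.128. The 2 transcripts with the smallest p had counts in every control library and 0 counts in every folate-lineage library, and neither passed the threshold. ENSRNOT00000082844.1, of 5109 bases, had 73, 139 and 85 counts in the control libraries, or 5.22 ± 2.22 CPM (SD, n = 3). Pooled over the group, its control level was 5.13 CPM. Against a floor of 3 counts over the whole folate-lineage group (0.0546 CPM), the pooled level there was at least 93.9-fold lower. ENSRNOT00000078317.1, of 1383 bases, had 137, 93 and 60 counts, or 5.02 ± 1.94 CPM (SD, n = 3), and was at least 91.7-fold lower by the same floor. The expected counts of both were fractional. The floor covers counting error only, so these folds do not allow for shared reads assigned to another transcript. DESeq2 gave them adjusted p-values of 1.59e-08 and 1.99e-08, and both were also called by edgeR with no filter on low counts (adjusted p = 0.0253 for each). On log2(TPM + 1) limma called the second alone (adjusted p = 0.0261).

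**Figure D2:**
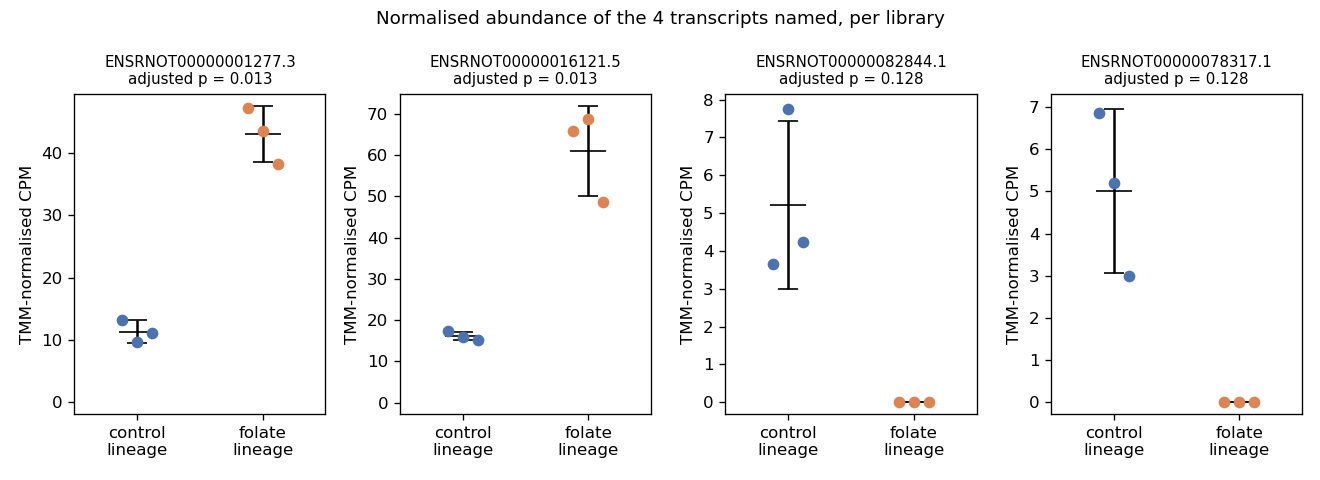
TMM-normalised CPM (y) of the 4 named transcripts in the control and folate lineages (x); points are libraries, the horizontal mark is the mean and the bar the SD of 3. ENSRNOT00000001277.3 and ENSRNOT00000016121.5 are higher in every folate-lineage library, and ENSRNOT00000082844.1 and ENSRNOT00000078317.1 have 0 counts in all 3 folate-lineage libraries at an adjusted p of 0.128.

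Transcripts that were absent from one lineage and present in the other were counted as a class, with a minimum of 10 counts in every library of the side that had them. There were 16 such transcripts, 6 present only in the folate lineage and 10 present only in the control lineage. The largest, of 684 bases, had 0 counts in the control libraries and 1378, 691 and 499 counts in the folate-lineage libraries. edgeR called 0 of the 16 (smallest adjusted p 0.128) and DESeq2 called all 16. Expected counts were fractional for each of the 16. The 9 splits of the 6 libraries that mixed the lineages gave 5 to 23 such transcripts, with a median of 15, and 3 of them gave 16 or more. The rank of the lineage split depended on the minimum, which was chosen after the data were examined. With a minimum of 5 counts there were 35 such transcripts, against 17 to 33 in the mixed splits, and with a minimum of 20 counts there were 9, against 3 to 13. DESeq2 calls with 0 counts on one side, with no minimum on the other, numbered 27 against 4 to 24 in the mixed splits.

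Small p-values were more frequent than 5% in the comparison of the lineages. An unadjusted p under 0.05 was reached by 1684 transcripts (9.66%) in edgeR, 899 higher and 785 lower in the folate lineage. The 9 splits that mixed the lineages gave between 1.78% and 6.38%. The groups did not overlap in log2 CPM for 16.2% of the transcripts. The 10% given by chance is an average over the 10 splits. This share was not computed for the mixed splits, so how far single splits stray from 10% is not known. The estimated changes were mostly small: the median was -0.0027 on the log2 scale, the middle 50% of transcripts lay between -0.18 and 0.19, and the 5th and 95th percentiles were -0.63 and 0.74.

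Abundant transcripts reached small p-values more often than rare ones. The share with p under 0.05 in edgeR was 4.20% of the 1335 transcripts under 1 CPM, 7.24% of the 6813 at 1 to 10 CPM, 11.9% of the 7749 at 10 to 100 CPM and 14.0% of the 1536 at 100 CPM and over. In the same order the median biological coefficient of variation was 59.9%, 35.1%, 14.1% and 10.3%. In the most abundant class 36.9% of the transcripts had a higher estimate in the folate lineage and the median log2 change was -0.05, whereas under 1 CPM 53.4% were higher and the median was 0.05. Transcripts with whole expected counts varied less (median coefficient 18.1%) than those with fractional counts (26.1%). In 5 equal classes of transcript length the median log2 change was, from the shortest class to the longest, -0.05, -0.01, 0.02, 0.02 and 0.01.

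The number of calls depended on the test. DESeq2 called 132 transcripts, 75 higher and 57 lower in the folate lineage, including both that edgeR called. limma voom called 2 and limma on log2(TPM + 1) called 9. Restricted to the 9611 transcripts with whole expected counts, an alternative added after the data were examined, edgeR called 9, of which 7 were higher (1.60-fold to 3.79-fold) and 2 lower (to 0.258 and 0.67 of the control level). These 9 include ENSRNOT00000001277.3 and were all called by DESeq2.

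**Figure D3:**
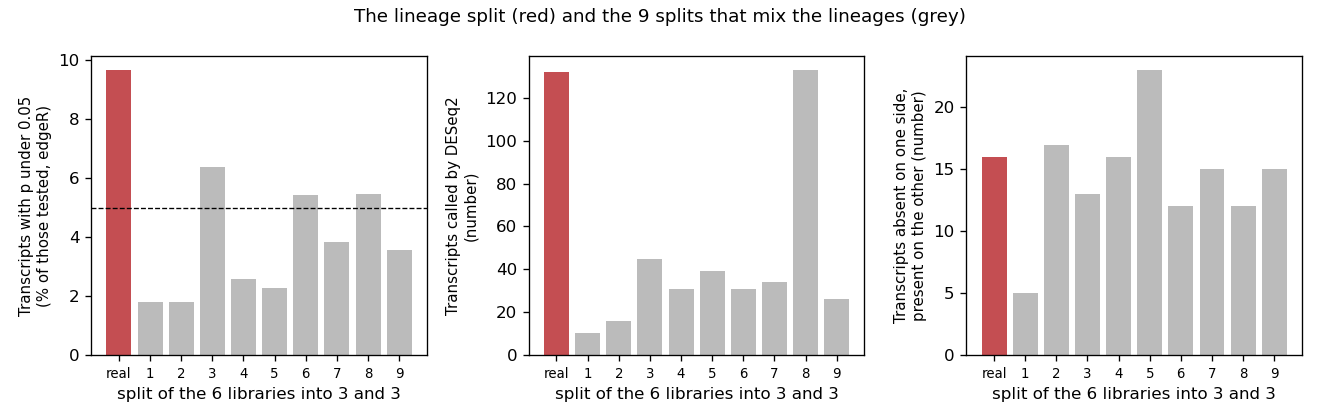
For the lineage split (red) and the 9 splits of the same 6 libraries that mix the lineages (grey, x), bars show the percentage of transcripts with p under 0.05 in edgeR (dashed line, 5%), the number called by DESeq2, and the number absent on one side with at least 10 counts in each library of the other. The lineage split is highest for small p-values (9.66% against at most 6.38%), is matched by a mixed split for DESeq2 (132 against 133) and is exceeded for absent transcripts at this minimum of 10 counts (16 against 23), though not at a minimum of 5 counts (35 against at most 33, not shown).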

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

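The count of 2 transcripts higher and 0 lower was the same with RLE or upper-quartile normalisation, with library sizes only, limma voom, no robust dispersion, at least 1 CPM in 3 libraries, an effective length offset, an adjusted p under 0.10 and a fold of at least 1.2, and each kept both transcripts. DESeq2 called 132 (75 higher, 57 lower), limma on log2(TPM + 1) 9 (8 higher, 1 lower), edgeR with no filter on low counts 4 (2 lower), and an adjusted p under 0.01 left 0. With the replicate block, edgeR called 4, all higher; same-numbered libraries did not deviate together and only 1 of 3 control libraries correlated best with its own number. Leaving out 1 library gave 0 to 3 calls (0 to 3 higher, 0 to 1 lower), and only without folate replicate 3 were both original calls among them; fewer libraries enter these fits. Settings added after the data were examined gave 9 calls with whole-number expected counts only (7 higher, 2 lower; 1 of the original calls among them), 3 with a count in every library, and 139 for DESeq2 without transcripts with a 0 (88 higher, 51 lower). The 16 transcripts absent from one lineage became 35 with a minimum of 5 counts in place of 10 and 9 with a minimum of 20, both also added afterwards; fewer transcripts meet a higher minimum. The cause of the other differences between settings was not tested, apart from what is given on DESeq2 among the other observations. No named transcript changed direction in its 17 alternatives. No scaling moved the median log2 change by more than 0.1. At this depth and n, recovery of simulated 1.5-fold changes by edgeR was 16.92% among transcripts with a mean of at least 1 CPM, so changes of that size were mostly not detectable. Set tests on gene lists, and leaving out sex-linked, haemoglobin and mitochondrial genes, were not run because no transcript could be tied to a gene.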

Other observations

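The tests on transcripts absent from one lineage with their count minimums, the setting restricted to whole-number counts and the use of the median over mixed splits were chosen after the results were seen; the tests on DESeq2 calls and on small p-values were set beforehand.

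Excess of small p-values. With 1684 transcripts at p under 0.05 in edgeR, the lineage split exceeded all 9 mixed splits, of which the highest had 1113. It also had the largest distance between groups, which comes from the same libraries and is not separate support. Many small differences that follow the lineage, most of them too small to call one by one, would give such an excess. Their number and size were not tested. Being the highest of 10 splits cannot set chance aside, since the smallest share that 10 splits allow is 0.1. The mixed splits are also not a clean baseline. Each has both lineages on both sides, so a lineage difference would widen the spread within its groups and could lower its count. The labels give no litter, sex or batch, so ancestry cannot be told apart from a litter, a sex ratio or a preparation batch shared by the 3 libraries of a lineage. Ancestry itself covers both the treatment of the F0 ancestors and their genotypes in this outbred stock. The labels do not separate these, so a difference between lineages cannot be assigned to folate. Among transcripts with whole expected counts the lineage split gave 9 calls against at most 2 in any other split, and 1 of the 10 splits (the real one) reached 9. The splits are too few for a share under 0.05.

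Presence and absence. By the rule first written for the 16 transcripts absent from every library of one lineage, a mixed split with as many counted against ancestry alone. That rule was itself written after the data were examined. At the minimum of 10 counts, 3 mixed splits gave as many or more, so by that rule the prediction for ancestry alone failed. Leaving the question open was decided after the values were seen, because the count minimum decides the comparison. At 10 counts mixed splits gave up to 23 of them, with a median of 15, and at 20 counts up to 13 against 9. At 5 counts the lineage split had the most, 35 against at most 33, and so it did for DESeq2 calls with 0 counts on one side, 27 against at most 24. The margins at 5 counts and for DESeq2 are small, and 10 splits are too few for a share under 0.05. Depth does not account for the 16, since 6 were absent from the control lineage and 10 from the folate lineage, and the depths of the lineages overlap. Of the 16, 100% had fractional expected counts, where the highest of 1000 draws matched on expression reached 87.5% and the median was 50%. A candidate explanation is that reads were assigned to one or another of several near-identical transcripts, which RSEM does afresh in each library. Whether sequence variants carried by these outbred animals decide that assignment was not tested.

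DESeq2 against edgeR. The 132 DESeq2 calls were richer in fractional counts than their matched draws (65.91% against at most 54.55%), so reads shared between transcripts may contribute to them. Summed over 3 simulations, DESeq2 also called more of the 51699 unchanged transcripts (198, or 0.383%) than edgeR (37, or 0.0716%). Beside these 198, DESeq2 recovered 59, 115 and 162 transcripts changed 1.5-fold, 2-fold and 4-fold. Beside its 37, edgeR recovered 34, 93 and 145. In these simulations, unchanged transcripts thus made up a larger share of the calls of both tools than the adjusted p threshold allows. By the rule set beforehand, a mixed split with as many calls as the lineage split counted against ancestry alone. A mixed split gave 133 calls against 132, so by that rule the prediction for ancestry alone failed. Leaving the question open was decided after the values were seen. The reasons were the margin of 1 call and the median of 31 over the 9 mixed splits. What sets that split apart from the other mixed splits was not tested, and whether ancestry accounts for the DESeq2 calls stays open.

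For the counts of calls in edgeR, 3 of the 10 splits gave 2 or more calls (highest other 5) and 2 gave 2 or more in one direction (highest other 3). On the lower side the real count was 0 (highest other 2), which all 10 splits reach by definition, so that count tests nothing. For DESeq2, 2 of the 10 splits gave 132 or more. With 10 splits no share under 0.05 can be reached.

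Length and library. The tested transcripts were parted by length into 5 equal classes, and each library was set against the mean of all libraries. The longest class minus the shortest was 0.17 on the log2 scale in control 1, 0.14 in folate 3 and -0.18 in control 3, and between -0.06 and -0.02 in the other 3 libraries. Across transcripts, Spearman's rho between length and the estimated change was 0.04 for the lineages and reached -0.23 in a mixed split.

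The effective length deficit was 236.43 ± 3.49 bases in the control libraries and 248.62 ± 9.85 in the folate-lineage libraries (SD, n = 3 each), with folate 1 and 2 at 255.27 and 253.28 and folate 3 at 237.3, inside the control range of 232.91 to 239.88 (exact permutation p = 0.2, two-sided, where 0.1 is the smallest possible).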
